A study of Mus musculus with 6 samples.

How the data were processed

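RNA was measured in stem cells sorted from the bone marrow of adult mice, in 3 wild type and 3 sti/sti libraries. Per the labels' protocols, the cells were sorted into lysis buffer, RNA was extracted with a column kit for small samples, and libraries were made with SMART-seq2. In its usual form that method does not mark strand and adds no molecular identifiers, so overlapping genes on opposite strands are not separated. The authors deposited 1 table of raw read counts per gene symbol, with 1 column per sample, and the values are whole numbers with a different total in each library. The submitters' processing notes name Bowtie 1.0.0, TopHat 1.4.1, HTSeq 0.7.1 and the mouse build mm10, without their roles. The gene annotation, the handling of reads with several matches, any read filter and any sequencing batch are not given in the sources used here. Each column was assigned to its sample by the sample's description label, and each sample to its group by its title and genotype label.

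The table holds 23337 symbols. For positions, transcript length and GC content, symbols were matched to GENCODE M21 on GRCm38, which has the coordinates of mm10: 20887 matched by the same symbol and 1884 through a RefSeq synonym. A further 510 had no match, 48 named several genes, 8 had no transcript sequence, and 25 symbols had the form of dates. Length and GC came from the principal isoform, or from the longest transcript where none is marked, and 98.5% of the tested genes had a length. No mitochondrially encoded gene was in the table, so that list was not tested. The list of sex-linked genes was not tested either, as 4 of its members remained after filtering and at least 5 were needed.

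Genes with low counts were removed with filterByExpr, which left 12167 genes. Counts were normalised with TMM factors and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, robust, genotype as the only term) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Standard errors of log2 fold changes were computed from the fold change and the F statistic and are approximate. Gene lists with at least 5 tested members were tested with camera in limma 3.58.1 at its preset correlation of 0.01, on log2 CPM with a prior count of 2, with adjustment over the 31 lists. Camera with an estimated correlation and fry were alternatives. For each list the mean log2 CPM per library gave a difference of list means with its SE. Shares of counts were compared with two-sided exact permutation tests, for which 3 against 3 libraries allow no p under 0.1.

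The gene lists, the tests, the other settings to try and the rule for named genes were fixed before the data were examined. The rule named up to 12 passing genes per direction with groups that do not overlap. As no gene passed, it named the 4 with the smallest p in each direction, 15 genes fixed by name, and up to 4 members per list with the smallest p. The other settings were different scalings, no filter and a stricter one (50 counts in 3 libraries), DESeq2 1.42.0, limma-voom with and without quality weights, each library left out, the replicate number as a block, no ribosomal protein genes, other set tests and other thresholds. DESeq2 was run on every gene with a count, without the filter. Offsets for transcript length and GC were added after seeing the data. They came from a smooth trend per library (mgcv 1.9.3, basis dimension 6) fitted to genes with a mean log2 CPM above 3 outside the ribosomal protein and respiratory chain lists.

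All 6 libraries were kept. All pairs of libraries, within and between genotypes, differed far beyond sampling noise (chi-square per degree of freedom from 43.4 to 82.4, Spearman's rho across genes from 0.96 to 0.964), so none was a repeat deposit. Depth was 16975134 to 24388990 counts per library. Some named genes had few counts in a library, with as few as 13 for Cdkn1a, 15 for Mki67, 50 for Slc1a4 and 0 for Chac1, so counting error adds to their spread. The common biological coefficient of variation was 0.467. On simulated data for this comparison (11895 genes tested, 5 simulations, 200 changed genes each above 5 CPM), the test recovered 40% of genes changed 2-fold and 78.2% of those changed 4-fold, and 4.98% of calls were false. With no list shifted, 0 lists were called. The simulated genes were drawn independently, so this count cannot show how often correlation between genes alone leads to a call. A simulated length trend of 0.1 per doubling alone, with no list shifted, gave the ribosomal protein list a median of -0.17 and called 2.2 lists on average. After the offsets these were 0.00 and 0. The simulated trend was linear in the same log2 length for all genes, so this shows only that a trend of that form is removed.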

Results

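Hematopoietic stem cells were sorted from adult C57BL6 mouse bone marrow as lineage-negative, Sca-1-positive, c-Kit-positive cells that carried CD150 and lacked CD48. Their RNA was profiled with SMART-seq2, a full-length cDNA method for small amounts of RNA that primes at poly(A) tails. The series compared 3 wild type libraries with 3 libraries homozygous for the sti allele of Aars. Aars encodes the alanyl-tRNA synthetase, and sti is a missense allele that weakens the enzyme's removal of amino acids wrongly attached to the alanine tRNA. The comparison addressed how this tRNA editing defect affected the stem cell transcriptome. The wild type libraries held 23150329, 24388990 and 22415103 counts, and the sti/sti libraries held 16975134, 17203072 and 22411359. Between 12769 and 13405 genes had a count in a library. The mean was 13178 ± 202 in wild type and 12914 ± 126 in sti/sti libraries (SD, n = 3 each). The groups did not overlap (two-sided exact permutation p = 0.1, the smallest possible). Depth was also lower in every sti/sti library than in every wild type library. At nearly equal depth, wild type replicate 3 had 13021 genes with a count and sti/sti replicate 3 had 12990. The shallower sti/sti replicate 2 had 12984. An effect of genotype on the number of genes with a count therefore cannot be told apart from depth. For the tests, 12167 genes were kept.

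The Aars transcript (chromosome 8, 111033144 to 111057664, GRCm38) was present at 90.2 ± 21.6 CPM (counts scaled to library size) in wild type and 103 ± 8.26 in sti/sti libraries (mean ± SD, n = 3 each). The log2 fold change was 0.19 (SE 0.193, edgeR quasi-likelihood adjusted p = 0.923). A missense allele need not alter the transcript level, so this value does not check the genotype labels. Ankrd16, which encodes a co-regulator of alanyl-tRNA synthetase editing, had a log2 fold change of -0.11 (SE 0.48, adjusted p = 0.988).

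Ribosomal protein genes, nuclear-encoded respiratory chain genes, interferon-responsive genes and proteasome genes were called lower as lists in sti/sti stem cells, and genes of the ATF4 pathway, which raises amino acid uptake and synthesis when translation is stressed, were called higher. These were 5 of 31 lists tested by camera with a preset correlation, and none was called with an estimated correlation (adjusted p = 0.569 for the ribosomal protein, respiratory chain and ATF4 lists, 0.592 for the interferon list and 0.878 for the proteasome list). Median log2 fold changes of the lists ran from -0.47 to 0.25. No single gene passed the threshold over all genes tested in edgeR, which found 817 at an unadjusted p under 0.05. DESeq2, run without the filter on low counts, called 144 and limma-voom 43.

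Of 78 ribosomal protein genes, 76 had a lower and 2 a higher estimate in sti/sti, with a median log2 fold change of -0.47 (camera adjusted p = 4.73e-37). The adjusted p was 0.569 with an estimated correlation, and the correlation estimated between these transcripts was 0.531. In edgeR no member passed over all genes and 74 were lower when adjusted over the list alone, while over all genes DESeq2 called 62 members and limma-voom 35. Rpl23a (chromosome 11, 78180932 to 78183584) averaged 660 ± 27.8 CPM in wild type and 408 ± 21.3 in sti/sti libraries. Rps7 had a log2 fold change of -0.58 (SE 0.0925) and Rps3a one of -0.51 (SE 0.0796). Together the ribosomal protein genes took 10.2% ± 0.362 of counts in wild type and 7.97% ± 0.43 in sti/sti libraries (SD, n = 3 each). The groups did not overlap (two-sided exact permutation p = 0.1, the smallest p that 3 against 3 allows). Ribosomal protein genes have many near-identical processed pseudogenes, and the treatment of reads that match several places is not given in the sources used here, so their levels are uncertain.

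The nuclear-encoded genes of the respiratory chain and ATP synthase were lower for 70 of 75 members (median log2 fold change -0.34, camera adjusted p = 1.28e-18), a call lost with an estimated correlation (adjusted p = 0.569). In edgeR none passed over all genes and 7 were lower when adjusted over the list alone, while over all genes DESeq2 called 5 members and limma-voom 1. Atp5g2, a subunit of the membrane part of ATP synthase, averaged 379 ± 20.5 CPM in wild type and 244 ± 24.6 in sti/sti libraries. Uqcrb of complex III had a log2 fold change of -0.89 (SE 0.2), and Cox8a of complex IV one of -0.52 (SE 0.117). Their share of counts was 1.87% ± 0.031 in wild type and 1.63% ± 0.0597 in sti/sti libraries (two-sided exact permutation p = 0.1, the smallest possible).

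Fold changes also moved with transcript length in 5608 genes outside these 2 lists with a mean log2 CPM above 5. The median log2 fold change was -0.27 for 81 genes with transcripts of up to 700 nt, and 0.11 for 556 genes with transcripts over 5000 nt. The ribosomal RNA precursor Rn45s took 0.159% ± 0.0346 of counts in wild type and 0.093% ± 0.0286 in sti/sti libraries (SD, n = 3 each, two-sided exact permutation p = 0.2). The slope on log2 length differed between genotypes by 0.10 per doubling (SE 0.0393, two-sided exact permutation p = 0.1, the smallest possible), and by up to 0.09 in other splits of the 6 libraries. Wild type replicate 2 (-0.01) and sti/sti replicate 1 (0.00) had nearly the same slope. Ribosomal protein transcripts had a median length of 803.5 nt and respiratory chain transcripts one of 868 nt, against 2619 nt for those 5608 genes. With the length and GC trend removed, the difference of list means went from -0.47 (SE 0.0692) to -0.28 (SE 0.0326) for ribosomal proteins and from -0.34 (SE 0.0648) to -0.18 (SE 0.0395) for the respiratory chain. Rpl23a went from -0.70 to -0.42, Atp5g2 from -0.64 to -0.38, Uqcrb from -0.89 to -0.55 and Cox8a from -0.52 to -0.25. Camera still called both lists lower (adjusted p = 5.89e-20 and 3.01e-06), and neither with an estimated correlation (adjusted p = 0.6 for both).

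**Figure D1:**
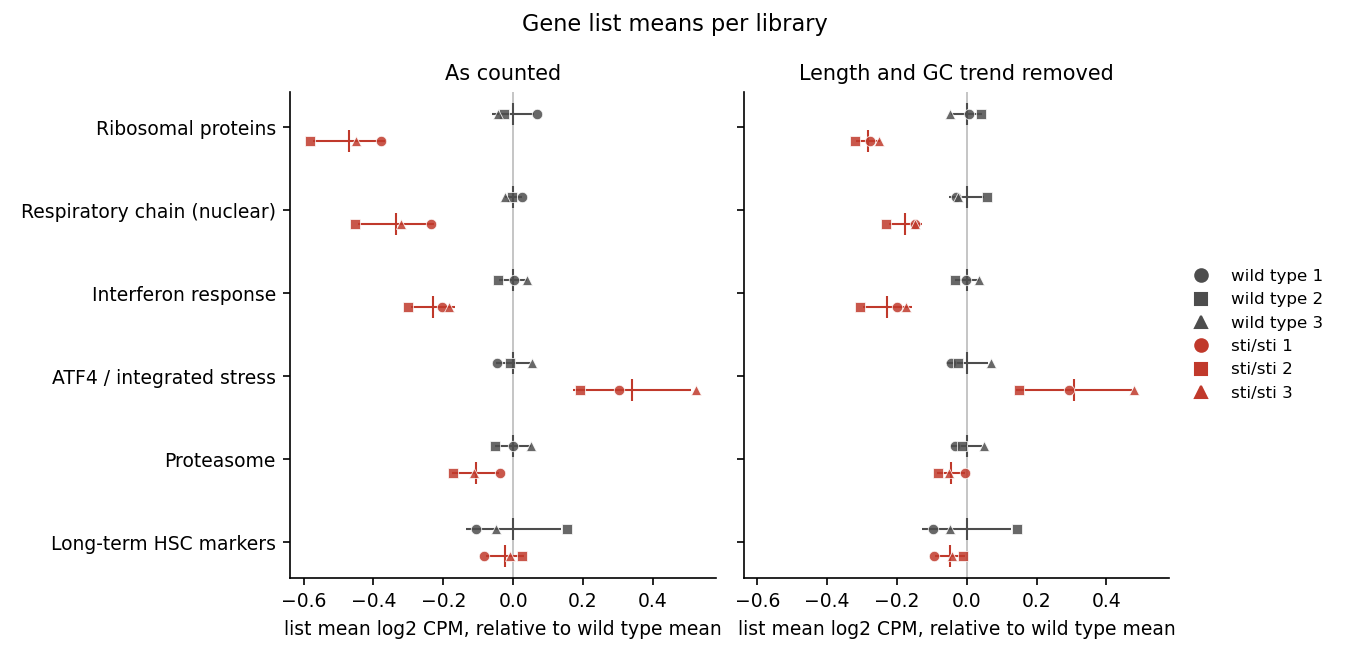
Mean log2 CPM of the members of 6 gene lists in each library, relative to the wild type mean, as counted (left) and with the trend on transcript length and GC removed (right). Points are libraries, and ticks with lines are group means ± SD (n = 3). The sti/sti libraries lay between -0.58 and -0.38 for ribosomal proteins as counted, and between -0.32 and -0.25 with the trend removed.

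**Figure D2:**
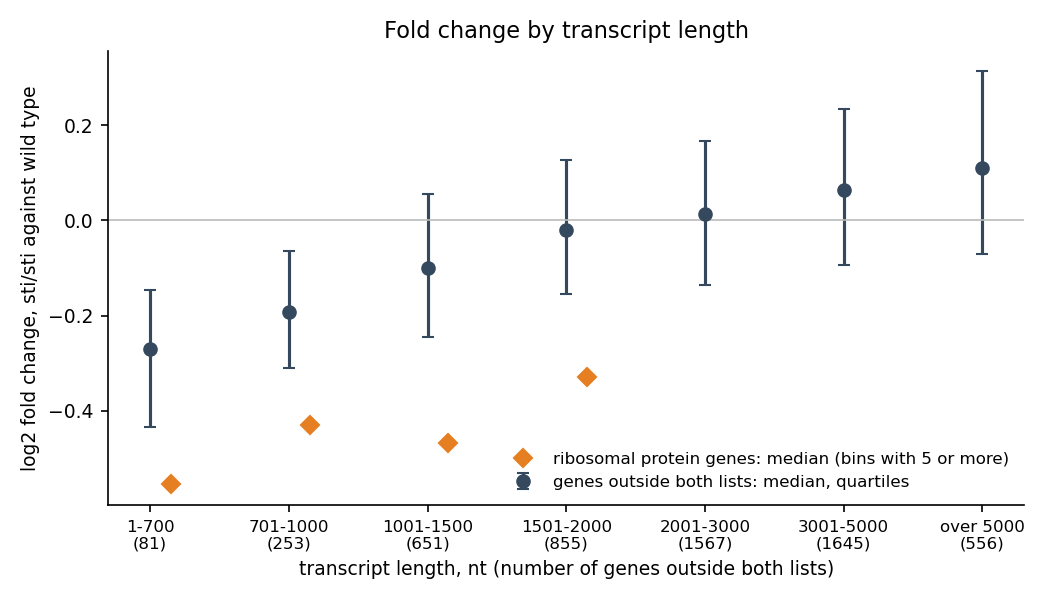
Log2 fold change of sti/sti against wild type by transcript length in nucleotides, with the number of genes in parentheses. Circles are medians and bars quartiles of 5608 genes with a mean log2 CPM above 5 outside the ribosomal protein and respiratory chain lists, and diamonds are medians of ribosomal protein genes in bins with at least 5 of them. Medians of the other genes ran from -0.27 in the shortest bin to 0.11 in the longest, and ribosomal protein genes of up to 700 nt had a median of -0.55.

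Of 29 ATF4 pathway genes, 19 had a higher and 10 a lower estimate in sti/sti (median log2 fold change 0.25, camera adjusted p = 0.0181). With an estimated correlation it was not called (adjusted p = 0.569). In edgeR none passed over all genes and 1, Slc1a4, was higher when adjusted over the list alone. Slc1a4 (chromosome 11, 20302180 to 20332713), a transporter of alanine, serine and other neutral amino acids, averaged 2.92 ± 0.717 CPM in wild type and 14.0 ± 3.95 in sti/sti libraries. Its log2 fold change was 2.26 (SE 0.505, edgeR adjusted p over all genes = 0.188), and DESeq2 called it over all genes (adjusted p = 0.00254). DESeq2 also called Chac1, a member that the filter on low counts had removed from the edgeR test (adjusted p = 0.0203), named here after its values were seen. Its DESeq2 log2 fold change was 7.83 (SE 2.07), and its lowest count in a library was 0. The size of this change is therefore uncertain, and the call may not rest on every sti/sti library. Mthfd2, of mitochondrial one-carbon metabolism, had a log2 fold change of 1.31 (SE 0.512), the asparagine synthetase gene Asns one of 0.47 (SE 0.197), and Psat1 of serine synthesis one of 0.31 (SE 0.129). Atf4 itself had 0.35 (SE 0.257), and the stress transcription factor Ddit3 had 0.09 (SE 0.344). With the length and GC trend removed the list was still called (adjusted p = 0.0217), and not with an estimated correlation as well (adjusted p = 0.6). Without sti/sti replicate 1 the median was 0.19 and the list was not called (adjusted p = 0.0733), nor was it without sti/sti replicate 3, where the median was 0.17 (adjusted p = 0.178).

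The 41 aminoacyl-tRNA synthetase genes and partners were not called as a list, with 26 higher and 15 lower estimates (camera adjusted p = 0.509). Over the list alone, 2 members passed, both higher. The cysteinyl-tRNA synthetase gene Cars (chromosome 7, 143557230 to 143600090) averaged 22.4 ± 1.73 CPM in wild type and 54.2 ± 20.6 in sti/sti libraries, with a log2 fold change of 1.28 (SE 0.308). The isoleucyl-tRNA synthetase gene Iars (chromosome 13, 49682100 to 49734267) averaged 81.1 ± 9.87 and 130 ± 17.8 CPM, with a log2 fold change of 0.69 (SE 0.171). Over all genes edgeR called neither, and DESeq2 called both (adjusted p = 0.0116 for Cars and 0.0206 for Iars).

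**Figure D3:**
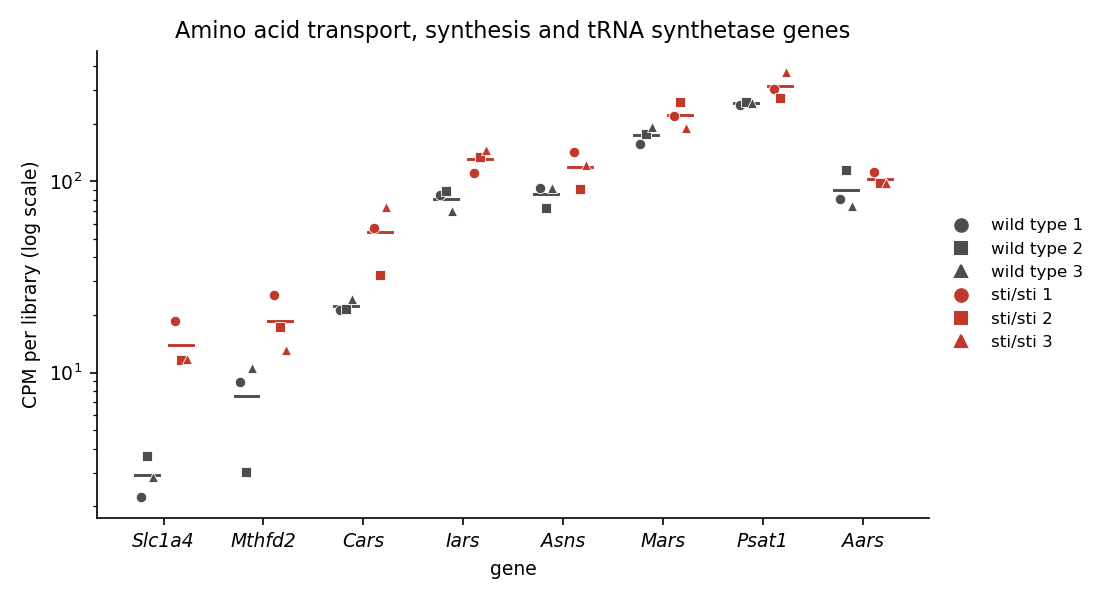
CPM per library, on a log scale, of 8 genes for amino acid transport, amino acid synthesis or tRNA charging. Points are libraries and horizontal lines are group means (n = 3). Slc1a4 averaged 2.92 CPM in wild type and 14.0 in sti/sti libraries, Cars 22.4 and 54.2, and Aars 90.2 and 103.

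Of 56 interferon-response genes, 45 had a lower and 11 a higher estimate in sti/sti (median log2 fold change -0.23, camera adjusted p = 0.00155). This call was lost with an estimated correlation (adjusted p = 0.592). In edgeR none passed over all genes and 1, Ly6e, was lower when adjusted over the list alone. Ly6e (chromosome 15, 74955051 to 74959905), a membrane protein that is also among the stem cell markers, had a log2 fold change of -0.42 (SE 0.0813), and DESeq2 called it over all genes (adjusted p = 0.00241). Ifitm3, an inhibitor of virus entry, had -0.42 (SE 0.125), and Oas3, a sensor of double-stranded RNA, -0.78 (SE 0.263). Ly6a, which encodes the sort marker Sca-1, averaged 351 ± 22.2 CPM in wild type and 276 ± 34.6 in sti/sti libraries (log2 fold change -0.35, SE 0.12, adjusted p = 0.578). With the length and GC trend removed, the log2 fold change was -0.29 for Ly6e, -0.20 for Ifitm3, -0.17 for Ly6a and -0.90 for Oas3. The call ended without wild type replicate 3, where the median was -0.14 (adjusted p = 0.0532), and without sti/sti replicate 2, where it was -0.17 (adjusted p = 0.0705). Wild type replicate 3 stood apart in sex-linked transcripts, with 1925 counts of Xist and 0 of Ddx3y, while the other 5 libraries held 0 to 45 of Xist and 229 to 748 of Ddx3y.

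The 48 proteasome genes had 36 lower and 12 higher estimates (median log2 fold change -0.09, camera adjusted p = 0.0234). The adjusted p was 0.878 with an estimated correlation, and no member passed over the list alone. The genes of the core particle subunits Psmb4 and Psmb7 had log2 fold changes of -0.44 (SE 0.165) and -0.42 (SE 0.17). The call ended with the length and GC trend removed, where the difference of list means went from -0.11 (SE 0.0495) to -0.05 (SE 0.0342) and the adjusted p was 0.608. It also ended without wild type replicate 1 (adjusted p = 0.0824), wild type replicate 3 (0.265), sti/sti replicate 2 (0.39) or sti/sti replicate 3 (0.121). Scaling by library size only and fry ended it as well, and 12 of 23 alternative settings kept it.

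Gene by gene, edgeR's quasi-likelihood test found 0 genes at an adjusted p under 0.05, with a smallest adjusted p of 0.0586. At an unadjusted p under 0.05 there were 817 genes, 373 higher and 444 lower, where chance gives 608. DESeq2 called 144 genes (34 higher, 110 lower) and limma-voom 43, all lower. Of these, 62 and 35 were ribosomal protein genes, and all 43 of limma-voom were among those of DESeq2. DESeq2 was run on every gene with a count, without the filter used for edgeR and limma-voom. Some of its calls were of genes that the filter had removed, and some had 0 counts in a library. Its count is therefore not over the same genes, although the 62 ribosomal protein genes it called were all in the edgeR test. The 4 lower genes with the smallest p did not pass in edgeR. They were Rpl23a with a log2 fold change of -0.70 (SE 0.0913, adjusted p = 0.0586), the histone variant gene H2afz with -0.61 (SE 0.0809, 0.0586), Tpt1, a translationally controlled growth protein, with -0.63 (SE 0.083, 0.0586), and Rpl21 with -0.52 (SE 0.0805, 0.091). Nor did the 4 higher genes with the smallest p, which were the nuclear receptor gene Hnf4a with 1.34 (SE 0.285, adjusted p = 0.154), Zxdc with 0.91 (SE 0.197, 0.17), Slc1a4, and the signalling adaptor gene Shc1 with 0.59 (SE 0.138, 0.213). The labels do not say that the 3 libraries of a genotype came from separate animals, so p-values measure the spread between these samples, which may be technical.

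Stem cell identity genes showed no shift as a group. Of 59 long-term stem cell genes, 31 had higher and 28 lower estimates (camera adjusted p = 0.932), with a median of 0.06, a difference of list means of -0.02 and the test's direction upward. Over the list alone 1 member passed, Ly6e. Tek, the angiopoietin receptor gene, had a log2 fold change of 0.87 (SE 0.25, adjusted p over all genes = 0.428), and Ctla2a one of -0.44 (SE 0.122, 0.388). The sort marker genes Slamf1 (CD150), Cd48 and Kit had log2 fold changes of -0.10 (SE 0.233), 0.04 (SE 0.513) and 0.22 (SE 0.209). The growth regulator gene Myc averaged 513 ± 68.7 CPM in wild type and 500.0 ± 29.1 in sti/sti libraries (log2 fold change -0.04, SE 0.114, adjusted p = 0.98). Fbxw7, of a ubiquitin ligase that targets Myc, had 0.72 (SE 0.548), and the cell cycle inhibitor genes Cdkn1a and Cdkn1c had -0.59 (SE 0.765) and 0.06 (SE 0.185).

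Folding and proliferation genes did not pass as lists. The cytosolic heat shock list had 25 lower and 12 higher estimates (camera adjusted p = 0.183). Its member Hsp90aa1, an abundant cytosolic chaperone, was the 1 that passed over the list alone, with 910 ± 19.1 CPM in wild type and 640 ± 14.5 in sti/sti libraries (log2 fold change -0.51, SE 0.0798, edgeR adjusted p over all genes = 0.091, DESeq2 1.12e-05). The unfolded protein response of the endoplasmic reticulum had 24 higher and 14 lower estimates (adjusted p = 0.669), and its chaperone gene Hspa5 had a log2 fold change of 0.31 (SE 0.11, adjusted p = 0.621). Translation initiation and elongation factors had 33 lower and 15 higher estimates (adjusted p = 0.0889), with Eef1d at -0.39 (SE 0.103) and Eef1a1 at -0.26 (SE 0.0712). G2/M genes had 34 lower and 17 higher estimates (adjusted p = 0.344), with Ccna2 at -0.92 (SE 0.272) and Mki67 at -0.69 (SE 0.798). G1/S genes (adjusted p = 0.725), cell cycle inhibitors (0.669), p53 targets (0.669), Myc and nucleolar targets (0.669), ribosome quality control and ubiquitin genes (0.669), and immediate early genes (0.669) were not called. NF-kB and inflammation genes (0.669), apoptosis regulators (0.932), autophagy and lysosome genes (0.786), glycolysis and hypoxia genes (0.792) and sterol synthesis genes (0.792) were not called either.

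Markers of the other cells that the sort could hold did not differ as lists. The camera adjusted p was 0.569 for megakaryocytes and platelets, 0.669 for stroma and endothelium, 0.705 for B cells, 0.725 for erythroid cells and 0.786 for multipotent progenitors. It was 0.786 for mast cells, basophils and eosinophils, 0.786 for neutrophil granules, 0.793 for monocytes, macrophages and dendritic cells and 0.876 for T and NK cells. The B cell and erythroid lists had a median and a difference of list means above 0 while the test pointed lower. The neutrophil and the ribosome quality control lists had a median just under 0 while the other values pointed higher, and the apoptosis list had a difference of list means just over 0 while the other values pointed lower. The iron exporter gene Slc40a1, from the macrophage list, averaged 16.9 ± 5.32 CPM in wild type and 39.2 ± 5.24 in sti/sti libraries (log2 fold change 1.21, SE 0.308, edgeR adjusted p = 0.295, DESeq2 0.0222).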

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

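The length and GC offsets and their combinations were chosen after seeing the data, and all other alternatives before. The count of 0 genes stayed at 0 with each library left out, with DESeq2 size factors, library size only, the length and GC offsets, without ribosomal protein genes, and with a log2 fold change of at least 1. It was 3 with upper quartile factors, 3 with no filter and 3 with the stricter filter, all lower. It was 144 with DESeq2, 43 with limma-voom, 50 with quality weights and 23 at an adjusted p under 0.1, and the full cause was not tested. DESeq2 was run without the filter on low counts, so part of its count comes from genes not in the edgeR test. The filter alone does not account for the gap, as edgeR without it called 3 genes and limma-voom with it 43. The count of 5 lists was 0 with camera at an estimated correlation, 0 with fry and 0 with offsets and an estimated correlation. Before adjustment, camera p at an estimated correlation was 0.0551 for ribosomal proteins, 0.0457 for the respiratory chain and 0.0301 for the ATF4 list. At that setting 0 lists were called in each of the 10 splits of the 6 libraries. Its 0 therefore does not set the real split apart. The full cause was not tested. The estimated correlation was 0.531 for ribosomal proteins. For the ATF4 list it was 0.00335, below the preset 0.01, so a higher correlation does not account for the loss of that call in camera. The count of lists was 3 to 6 with each library left out. It was 3 without wild type replicate 3, sti/sti replicate 2 or sti/sti replicate 3. With offsets and no wild type replicate 3 it was also 3. Other settings gave 4 to 7 lists. Ribosomal protein and respiratory chain calls held in all 6 fits with a library left out, the ATF4 and interferon calls in 4 each and the proteasome call in 2. The Aars log2 fold change passed in no setting and ranged from 0.05 with the offsets to 0.40 without wild type replicate 2.

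Of the other results, 28 list values lost a call, 9 list values and 47 gene values gained one, and no called result changed direction. As the main fit called no gene, none could lose a call. Directions of results called in neither setting are not counted as changes; 75 such values changed sign. No scaling moved the median of all genes by over 0.1, with 0.06 for library size only. Same-numbered samples are not said to be paired, and their deviations from the group means correlated by 0.0404, 0.0478 and 0.0276, so the numbers were not taken as pairs, although each wild type library correlated best with its own number, a hint from the data. The replicate block gave 0 genes, 5 lists and an Aars log2 fold change of 0.21, and with the offsets 0 genes and 4 lists. Depth limits genes with few counts, such as Cdkn1a, with as few as 13 in a library.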

Other observations

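The tests of length and GC for the ribosomal protein and respiratory chain lists, the lists of cytosolic and mitochondrial synthetases, mitochondrial ribosome, splicing genes and other TOP mRNAs, and the count of splits for genes were chosen after results were seen. Split by compartment, 16 of 20 cytosolic aminoacyl-tRNA synthetase genes had higher estimates in sti/sti (difference of list means 0.20, SE 0.0283, camera adjusted p over these 5 added lists = 0.0112). The adjusted p was 0.116 with an estimated correlation. Cars and Iars led the list and were the 2 members that passed over the list alone. The median log2 fold change of the list was 0.13, below its difference of list means. Mars, for methionine, had a log2 fold change of 0.34 (SE 0.147). Other members moved little, such as Gars with 0.01 (SE 0.115), Tars with 0.07 (SE 0.228) and Wars with 0.11 (SE 0.118). Of 17 mitochondrial synthetase genes, 8 had higher and 9 lower estimates (difference -0.05, SE 0.092, adjusted p = 0.906). With the length and GC trend removed, the cytosolic difference was 0.15 (SE 0.0386, median log2 fold change 0.09, adjusted p = 0.0328, and 0.151 with an estimated correlation) and the mitochondrial one -0.09 (SE 0.0964), a gap of 0.24 (SE 0.114). Many cytosolic synthetase genes are known targets of ATF4, so a candidate explanation is a shared response with the ATF4 list. The lists share 0 members, and the link itself was not tested.

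Of 73 mitochondrial ribosome genes, 62 had lower estimates (difference of list means -0.19, SE 0.0594, camera adjusted p = 3.85e-06), and of 30 Sm and Lsm splicing genes 25 did (-0.26, SE 0.0637, adjusted p = 3.37e-05). The adjusted p was 0.164 and 0.116 with an estimated correlation. Both were still called by camera with the length and GC trend removed (adjusted p = 0.0139 for both), at -0.11 (SE 0.0339) and -0.16 (SE 0.0466). Neither was called with an estimated correlation as well (adjusted p = 0.151 for both). These differences lay less than 2 SE beyond 0.1 log2, so the trend and a separate change cannot be told apart.

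Ribosomal protein and respiratory chain mRNAs were called lower in sti/sti at the preset correlation and not at an estimated one (adjusted p = 0.569 for both, and 0.6 with the trend removed). The sti/sti libraries also had relatively fewer counts from short transcripts. For ribosomal proteins the tables argue against the length and GC trend as the whole cause, since the difference of list means was -0.28 (SE 0.0326) with the trend removed, and against the library with Xist counts, since it was -0.49 (SE 0.0768) without wild type replicate 3. For the respiratory chain, -0.18 (SE 0.0395) remained, less than 2 SE beyond the 0.1 set as the bound, and the trend and a separate change cannot be told apart. A sequencing batch, which the labels do not give, and reads shared with pseudogenes, whose handling is not given, stay open. So does a length trend that is stronger in abundant transcripts, as the offsets had no term for abundance.

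As a hypothesis, ribosomal protein mRNAs may be lower together with other mRNAs that carry a terminal oligopyrimidine (TOP) motif, which growth signals regulate as 1 class. The counts do not measure translation, and a role of growth signals was not tested. In 13 such mRNAs, of which 7 belonged to the translation factor list whose direction was already known, 12 had lower estimates, the difference was -0.19 (SE 0.0406) with the trend removed, and the camera adjusted p of 0.007 became 0.151 with an estimated correlation.

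ATF4 pathway mRNAs were called higher in sti/sti at the preset correlation, and not at an estimated one (adjusted p = 0.569, and 0.6 with the trend removed) or by fry (0.0789). As the whole cause, the length and GC trend is argued against by a difference of 0.31 (SE 0.102) with the trend removed. The library with Xist counts is argued against by one of 0.47 (SE 0.154) without wild type replicate 3. That fit filtered genes anew, so its list members may differ and the 0.47 does not show a larger effect. Its median log2 fold change was 0.20, against 0.25 with all libraries. The call rests on 3 sti/sti libraries that differ in size of the effect, and was lost without sti/sti replicate 1 (adjusted p = 0.0733) or sti/sti replicate 3 (0.178). A response to mistranslation in sti/sti cells, a batch and the time between harvest and lysis stay open and may each contribute.

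Interferon-response mRNAs were called lower in sti/sti at the preset correlation, and not at an estimated one (adjusted p = 0.592, and 0.6 with the trend removed) or by fry (0.286). As the whole cause, the trend on length and GC is argued against by a difference of -0.23 (SE 0.0449) with the trend removed. A part played by wild type replicate 3, whose Xist counts may mark female cells, cannot be told apart from genotype: without it the difference was -0.21 (SE 0.0435) and the camera adjusted p 0.0532, with 2 wild type libraries left. Differences in housing or exposure between animals stay open, as does an effect of the genotype.

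The 6 libraries can be split into 3 and 3 in 10 ways, so the share of splits as large as the real one cannot fall under 0.1. For genes passing in edgeR, the real split gave 0 and the highest other split 0, so that 10 of 10 splits gave as many follows from the count of 0 and says nothing about chance. For lists, the real split gave 5 and the highest other 5, and 3 of 10 splits gave as many, the real one included. With the length and GC trend removed, the real split gave 4 lists and the highest other 5. At an unadjusted p under 0.05 the real split gave 817 genes and the highest other 596. The absolute ribosomal protein median was 0.47 in the real split and at most 0.25 in the others, and with the length and GC trend removed 0.29 and at most 0.16. With the trend removed, the absolute ATF4 median was 0.19 in the real split and up to 0.18 in the others, and the ATF4 adjusted p was 0.0217 in the real split and at lowest 0.193 in the others.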
